A study of Mus musculus with 24 samples.

How the data were processed

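RNA was measured in 24 libraries from sorted epithelium of colon and ileum of 12 C57BL/6 mice aged 8 to 14 weeks. Per the labels' protocols, 100 ng of RNA went into a stranded total RNA kit with ribosomal depletion, and libraries were sequenced as single-end reads of 50 bp on 3 lanes. The molecule label says polyA RNA, which disagrees with that kit and could not be settled. Which library ran on which lane is not given in the sources used here, so no lane effect could be tested. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with HISAT 0.1.6 and counted with HOMER on the mouse build mm9. The reference at hand was another build, so no coordinates are given. Whether counting used strand is not given, so overlapping and antisense genes such as Plet1os are uncertain.

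The table deposited by the authors held 1 coverage signal per gene and library, as reads divided by a size factor, with 1 decimal, for 24421 genes. Each of the 24 columns matched 1 library by its label. In each library the low values were whole multiples of 1 step, the value of 1 read, which lay between 0.698 and 2.22. Dividing by it gave whole numbers within 0.05 normalised reads for 99.3 to 100.0% of the low values. Median-of-ratios factors computed from the recovered reads, times that step, gave 0.9999 to 1.0000, so the deposited scaling equalled median-of-ratios scaling over all 24 libraries. The symbol Secisbp2 stood in 2 rows, which were kept apart. Recovered reads per library were 8.32 to 18.7 M, of which Rn45s took 0.0642 to 29.4%. Counting error is largest for the genes near the filter, and the spread between mice came on top.

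Replicates were separate mice by their numbers. Any pair of replicates differed by a chi-square of at least 18.2 per gene, and any of the 276 pairs of libraries by at least 15.4, so no library had been deposited under several names, and log2 values of replicates correlated at 0.953 to 0.986 across genes. Colon and ileum samples with the same number came from the same animal per the labels, which pairs them. The deviations of a mouse's colon and ileum from their group means correlated at -0.59 to 0.69 across genes (median 0.30), above 0.1 in 5 of 10 mice. The 2 WT irradiated mice were left out, because in a group of 2 the deviations are mirror images and both mice have the same value (0.81).

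The tests set before the data were examined assumed counts. Since the file held normalised values, the form set for that case was used, limma 3.58.1 in R 4.3.3 with a trend on log2(value + 1). Genes with at least 10 normalised reads in at least 2 libraries were tested. Comparisons within a tissue used all libraries of that tissue as 4 groups with 1 shared spread, because WT irradiated had 2 mice. Colon against ileum and the interactions used all 24 libraries. p-values were adjusted by Benjamini-Hochberg over genes, with calls under 0.05. Without any change, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. There were 11 comparisons. Gene lists (26 lists, 395 genes, 394 of them in the file) were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The design had set camera on log2 CPM, and it was run on log2(value + 1) instead, as the gene tests were. Median-of-ratios scaling, set as an alternative, is the deposited scaling itself. In the 6 within-tissue comparisons involving KO groups, 58 list calls passed at the preset correlation and none at the estimated one. The lowest adjusted p there was 0.0661.

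Genes were named by a rule set beforehand. In each comparison it took the 6 higher and 6 lower genes with the largest change among those called, with a mean of at least 5 reads per M and no overlap between the groups, passing over predicted-only names. The overlap condition did not apply to interactions. It added the 2 called members with the smallest p of each list, and 13 preset genes in every KO comparison where they passed the filter. Cxcl1, Cxcl5 and S100a8 did not pass it in ileum and were not tested there. A gene that this rule named is not reported here and was not replaced, while counts of called genes include all genes tested. Reads per M were computed from column totals without Rn45s. Lrg1, Pim1, Igtp, Nts and Slc37a2 in KO late colon fell outside it and were named after their values were seen, as the remaining members of small counts. S100a9 and the genes named under the other observations were also chosen later.

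On simulated counts with 200 changed genes, drawn 5 times for KO late against WT irradiated colon with 19145 genes, limma recovered 4.18% of genes changed 2-fold, 55.2% changed 4-fold and 94.5% changed 16-fold, with 5.60 false calls among 107.8. For KO early against WT irradiated ileum with 19122 genes these shares were 6.57, 66.3 and 95.8%. Genes were drawn independently, without structure shared between libraries, so these shares and the false calls may not carry over to the real libraries. Alternatives set beforehand were DESeq2 1.42.0 on recovered reads, pseudocounts of 0.1 and 5, no filter, a filter of 1 read per M, fits of only the groups compared, WT non-irradiated controls, the mouse as a block and leaving out each mouse. Added after seeing the data were edgeR 4.0.16 quasi-likelihood tests on the recovered reads, TMM scaling, a filter of a mean of 100, and a covariate of log2 reads per M in 1462 olfactory and vomeronasal receptor genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.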

Results

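The series profiled RNA from sorted intestinal epithelial cells of mice, taken as CD45-negative cells that carried a tomato reporter driven by Villin, a structural protein of the epithelial brush border. Colon and ileum were taken from the same 12 mice, which gave 24 libraries. The groups were KO chimeras 2 weeks after chimerism (KO early, n = 4 mice), KO chimeras at 8 weeks (KO late, n = 3), irradiated wild-type mice at 8 weeks (WT irradiated, n = 2) and wild-type mice that were not irradiated (WT non-irradiated, n = 3). The series title names IL-10Rα-deficient gut macrophages and an IL-22-driven epithelial response, while the sample labels only say KO. The series design text speaks of colonic macrophages, although every sample is labelled as epithelium. Each library held 8.32 to 18.7 M reads assigned to genes (median 13.2 M). Values below are reads divided by a size factor per library, called normalised reads, and are given as mean ± SD. Fold changes are on the log2(value + 1) scale, which understates changes of low genes.

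Il10ra, the receptor chain named in the title, was low in the epithelium of every group. It had 23.8 ± 2.47 normalised reads in KO early colon (n = 4), 23.6 ± 8.19 in KO late colon (n = 3), 15.4 ± 7.71 in WT irradiated colon (n = 2) and 11.7 ± 7.80 in WT non-irradiated colon (n = 3). In ileum it had 25.3 ± 4.09, 7.50 ± 3.12, 7.05 ± 2.19 and 7.33 ± 5.65 in the same order. None of the 4 comparisons of KO with WT irradiated called Il10ra. In chimeras made by transfer of blood-forming cells the epithelium keeps the genotype of the recipient, so this gene did not check the KO label in these cells. Il22ra1, the epithelial chain of the IL-22 receptor, had 1577 ± 543 normalised reads in KO early colon, 1563 ± 498 in KO late colon and 2089 ± 606 in WT irradiated colon, and was not called either.

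**Figure D1:**
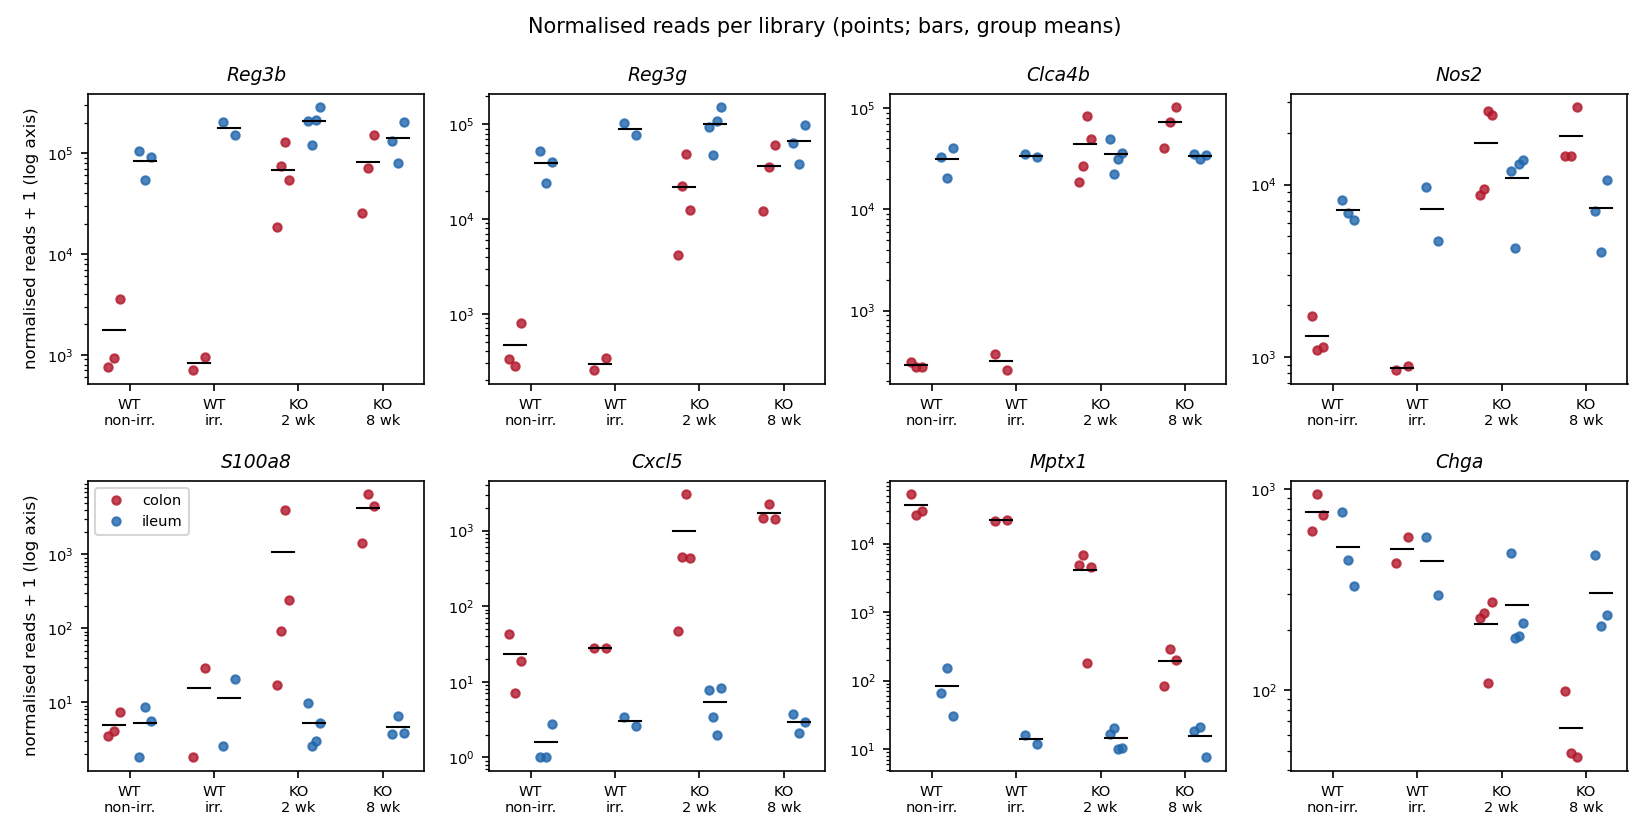
Normalised reads plus 1 on a log axis for 8 genes, with 1 point per library, bars for group means, colon in red and ileum in blue. Colon of both KO groups lay above both WT groups for Reg3b, Reg3g, Clca4b and Nos2, and in KO late colon Mptx1 had a mean of 189.5 against 21856 in WT irradiated colon.

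The comparison of KO late with WT irradiated colon asked what 8 weeks of chimerism with the knockout did to the colonic epithelium at a matched time. Reg3b, an antimicrobial C-type lectin, had 82052 ± 62753 normalised reads in KO late (n = 3) against 826 ± 176 in WT irradiated (n = 2), a log2 fold change of 6.30 ± 0.83 (SE, adjusted p = 0.00280). Reg3g, its close relative, rose by 6.66 ± 0.83 (adjusted p = 0.00205). Clca4b, of the family of calcium-activated chloride channel regulators, rose 217-fold, from 314 ± 82.2 to 72303 ± 31641 (log2 7.76 ± 0.53, adjusted p = 1.58e-05). Mptx1, a mucosal pentraxin, fell from 21856 ± 167 to 189.5 ± 102 (log2 -7.02 ± 1.13), and Ang4, an antimicrobial ribonuclease, fell from 3726 ± 1470 to 59.9 ± 39.4 (log2 -6.08 ± 0.91).

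Of 22 measured members of the list of antimicrobial and IL-22 response genes, 8 rose, none fell and 14 did not pass over all genes tested, and adjusted over the list alone 11 rose and 1 fell. Beside the Reg3 genes these were S100a8, a subunit of the neutrophil and epithelial protein calprotectin (log2 8.91 ± 1.65), Steap4, a metalloreductase (4.45 ± 0.45), Nos2, the inducible nitric oxide synthase (4.41 ± 0.49), Lcn2, a siderophore-binding protein (4.69 ± 0.83), Lrg1 and Pim1. Saa1, Saa3, Fut2, Duox2 and Socs3 had adjusted p from 0.149 (Socs3) to 0.724 (Saa1). Of 14 chemokines, 6 rose, with Cxcl2 at 6.12 ± 1.07, Cxcl5 at 5.92 ± 1.17 and Cxcl1 at 4.65 ± 0.91, all of them ligands for neutrophil receptors. Cxcl3 was at 0 in both WT irradiated libraries and at 99.97 in KO late, at least 42.5-fold higher when 3 reads per library are taken as the floor. Lcn2 and Cxcl2 had means of 1.5 and 6.3 normalised reads in WT irradiated colon, so the size of their changes depends on the pseudocount too. Of 28 interferon response genes, 3 rose, namely Ifit2 (2.81 ± 0.41), Iigp1 (3.27 ± 0.68) and Igtp. Nox1, an epithelial oxidase, was the only one of 9 oxidase genes to pass (1.80 ± 0.39). By camera with a preset correlation these lists stood above other genes, with adjusted p of 4.94e-08, 1.93e-06, 8.96e-07 and 0.0171. With an estimated correlation the adjusted p were 0.432, 0.189, 0.652 and 0.652.

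Some markers of differentiated cells fell in the same comparison. Of 15 enteroendocrine genes, 3 fell, namely Chga, the granule protein chromogranin A (log2 -3.03 ± 0.42), the hormone gene Pyy (-2.83 ± 0.50) and Nts, and the camera adjusted p was 0.00229 (adjusted p = 0.652 with an estimated correlation). Of 15 colonocyte genes, 3 fell, namely Mptx1, the phosphate transporter Slc20a1 (-3.41 ± 0.53) and Slc37a2, with a camera adjusted p of 0.00762 (adjusted p = 0.663 with an estimated correlation). With receptor reads as a covariate the goblet list changed sign, from a median of -0.77 to 0.41, and the colonocyte list moved from -0.92 to -0.36, while the enteroendocrine list moved from -1.25 to -2.05. The goblet and colonocyte calls were lost (camera adjusted p = 0.233 and 0.705), and the enteroendocrine call stayed at the preset correlation (camera adjusted p = 1.25e-07). Klk1 (-2.47 ± 0.52) was the only one of 14 goblet cell genes to pass (list camera adjusted p = 0.00762, adjusted p = 0.663 with an estimated correlation), and Trpm5 (-1.67 ± 0.30) the only one of 12 tuft cell genes. The ileal bile acid transporter Slc10a2 (-2.78 ± 0.47) fell too. In the Paneth list Ang4 fell and Mmp7, a protease that processes defensins, rose (3.05 ± 0.57), and that list's median (0.81) and mean (-0.14) differed in sign. In the list of xenobiotic and retinoid metabolism Cyp4b1 fell (-2.93 ± 0.60) and Dhrs9 rose (2.22 ± 0.43), with a camera adjusted p of 0.0171 for this list and for MHC class I presentation (adjusted p = 0.652 and 0.741 with an estimated correlation). With the covariate the median of this list moved from -0.60 to -0.70 and the call was lost (camera adjusted p = 0.0799). The median of MHC class I presentation moved from 0.65 to 1.78 (camera adjusted p = 1.79e-16). Both values with the covariate are at the preset correlation of 0.01, and no estimated correlation was run there. In the fit without it the estimated correlation of the MHC class I members was 0.87. The other large declines were Sycn (-5.00 ± 0.86), Sult1a1 (-4.67 ± 0.98), Prss23 (-4.45 ± 0.60) and Efna3 (-4.29 ± 0.88). No member of the leukocyte, myeloid or stromal marker lists passed, though their medians were 0.79, 0.69 and 0.78 and their camera adjusted p 0.00229, 0.0171 and 0.0246 (adjusted p = 0.652, 0.663 and 0.663 with an estimated correlation). With the covariate these medians were -0.053, -0.074 and -0.0025, and the 3 list calls were lost (camera adjusted p = 0.609, 0.830 and 0.510). KO late colon libraries also carried more reads in olfactory and vomeronasal receptor genes, used here as a measure of background although some of them are found in gut endocrine cells, at 943 ± 166 per M reads against 413 ± 253 in WT irradiated colon.

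In all, limma called 197 of 19145 genes (123 higher, 74 lower), while edgeR on the recovered reads called 164, split into 76 higher and 88 lower, and DESeq2 called 768 (324 higher, 444 lower). The balance also turned with WT non-irradiated controls (196 higher, 280 lower) and with both WT groups as control (309 higher, 479 lower). The count was 103, 60 and 96 without KO mice 49, 50 and 57, and 11 and 43 without WT mice 59 and 61, and 82 with receptor reads as a covariate (71 higher, 11 lower).

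The comparison of KO early with WT irradiated colon asked what was already changed at 2 weeks, with controls taken at 8 weeks, so that time was not matched. The leading genes were again Clca4b (log2 6.94 ± 0.50, 44673 ± 29176 normalised reads, n = 4, adjusted p = 3.45e-05), Reg3b (6.08 ± 0.79, adjusted p = 0.00490) and Reg3g (5.71 ± 0.79). Lrg1 (6.05 ± 1.08), Ly6c1 (5.24 ± 0.84) and Ces2f, a carboxylesterase (5.08 ± 0.66), rose as well. Lrg1 had a mean of 2.4 normalised reads in WT irradiated colon, so the size of its change depends on the pseudocount. Of 22 antimicrobial and IL-22 response genes, 6 rose and none fell, among them Nos2 (4.16 ± 0.46), Steap4 (3.33 ± 0.42) and Saa3 (2.28 ± 0.38), and adjusted over the list alone 12 rose and 1 fell. Its camera adjusted p was 1.43e-22 (adjusted p = 0.0661 with an estimated correlation). No chemokine or oxidase gene passed over all genes, while their lists had camera adjusted p of 0.00234 and 1.41e-05 (adjusted p = 0.399 and 0.328 with an estimated correlation). Cxcl5 had 1000 ± 1397 normalised reads (adjusted p = 0.333) and S100a8 had 1073 ± 1917 (adjusted p = 0.484), with 1 library at 3945 for the latter. Lcn2, Fut2, Socs3, Saa1, Duox2 and Cxcl1 had adjusted p between 0.0599 (Socs3) and 0.932 (Saa1).

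In KO early colon the lists of MHC class I (median log2 fold change 0.77) and class II (0.94) presentation, cholesterol synthesis (0.59) and the unfolded protein response (0.72) had camera adjusted p of 2.25e-05, 0.00791, 2.73e-05 and 8.58e-05, and no member of them passed over all genes. With an estimated correlation their adjusted p were 0.505, 0.554, 0.505 and 0.505. The goblet (-0.73) and tuft cell (-0.44) lists lay lower, with camera adjusted p of 0.00234 and 0.00393 (adjusted p = 0.554 and 0.468 with an estimated correlation). The cell cycle, ileal bile acid, xenobiotic and myeloid lists also passed camera at the preset correlation and not at the estimated one. Among the genes that fell were Prss23 (-3.52 ± 0.57), Edn1, the precursor of endothelin (-2.90 ± 0.46), Slc43a3 (-2.02 ± 0.35), Plekha1 (-1.79 ± 0.32) and Cd83 (-1.74 ± 0.31). limma called 39 genes (32 higher, 7 lower) against 31 by edgeR and 229 by DESeq2. The count was 3 and 4 without WT mice 59 and 61, 73, 18 and 25 without KO mice 100, 118 and 120, 23 when only these groups were fitted and 100 with receptor reads as a covariate. The excess of higher genes shrank with WT non-irradiated controls (58 higher, 49 lower) and with both WT groups as control (112 higher, 95 lower).

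Both KO groups shared calls in colon. Of the 32 genes higher in KO early and the 123 higher in KO late, 26 were the same, against 0.206 for independent lists, and of the 7 and 74 lower genes 5 were the same, against 0.0271. Both comparisons used the same WT irradiated libraries. With KO late set against WT non-irradiated mice, so that no control library was shared, 28 higher and 5 lower genes were shared, against 0.328 and 0.102 for independent lists. With KO early set against WT non-irradiated mice these counts were 40 and 16, against 0.373 and 0.189. All these comparisons drew on 1 shared spread per gene over the colon libraries, so the lists were not fully independent even then. Across 19145 genes, which are not independent replicates, the log2 fold changes correlated at 0.72 with a covariance of 0.288. In 20 draws with every colon library, controls included, simulated around the WT irradiated mean, these were 0.64 and 0.133. Genes were drawn independently and group sizes largely set that correlation, so it does not cover structure shared between libraries. With KO late or KO early set against WT non-irradiated mice, the observed correlations were 0.60 and 0.68.

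The comparison of KO late with KO early colon asked what changed between 2 and 8 weeks. Pyy was the only gene called, at 5.53 ± 4.58 normalised reads in KO late (n = 3) against 55.3 ± 17.6 in KO early (n = 4), a log2 fold change of -3.28 ± 0.42 (adjusted p = 0.0375). The enteroendocrine list lay lower (median -0.87, 4 lower adjusted over the list alone, camera adjusted p = 6.91e-05, adjusted p = 0.445 with an estimated correlation). Chemokines (median 1.45, 6 higher adjusted over the list alone) and interferon response genes (0.67, 8 higher) lay higher, with camera adjusted p of 2.93e-05 and 2.85e-07 (adjusted p = 0.204 and 0.749 with an estimated correlation). Cell cycle genes (-0.55) and ileal bile acid genes (-1.77) lay lower, with camera adjusted p of 2.02e-06 and 3.47e-05 (adjusted p = 0.749 and 0.204 with an estimated correlation). The colonocyte, cholesterol and leukocyte lists also passed camera at the preset correlation and not at the estimated one. S100a8, called in KO late and not in KO early against WT irradiated colon, differed between them by 4.15 ± 1.38 (adjusted p = 0.388). The receptor background was 943 ± 166 per M reads in KO late and 554 ± 110 in KO early. At an unadjusted p under 0.05 limma gave 2065 genes, edgeR called 0 and DESeq2 199. Without mouse 118 limma called 16 genes, without mouse 117 it called 1, and without mouse 49, 50, 100 or 120 it called 0. Pyy passed without mouse 57 or 118 and not without 117 (adjusted p = 0.0615), 49, 50, 100 or 120 (adjusted p from 0.135 to 0.365).

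**Figure D2:**
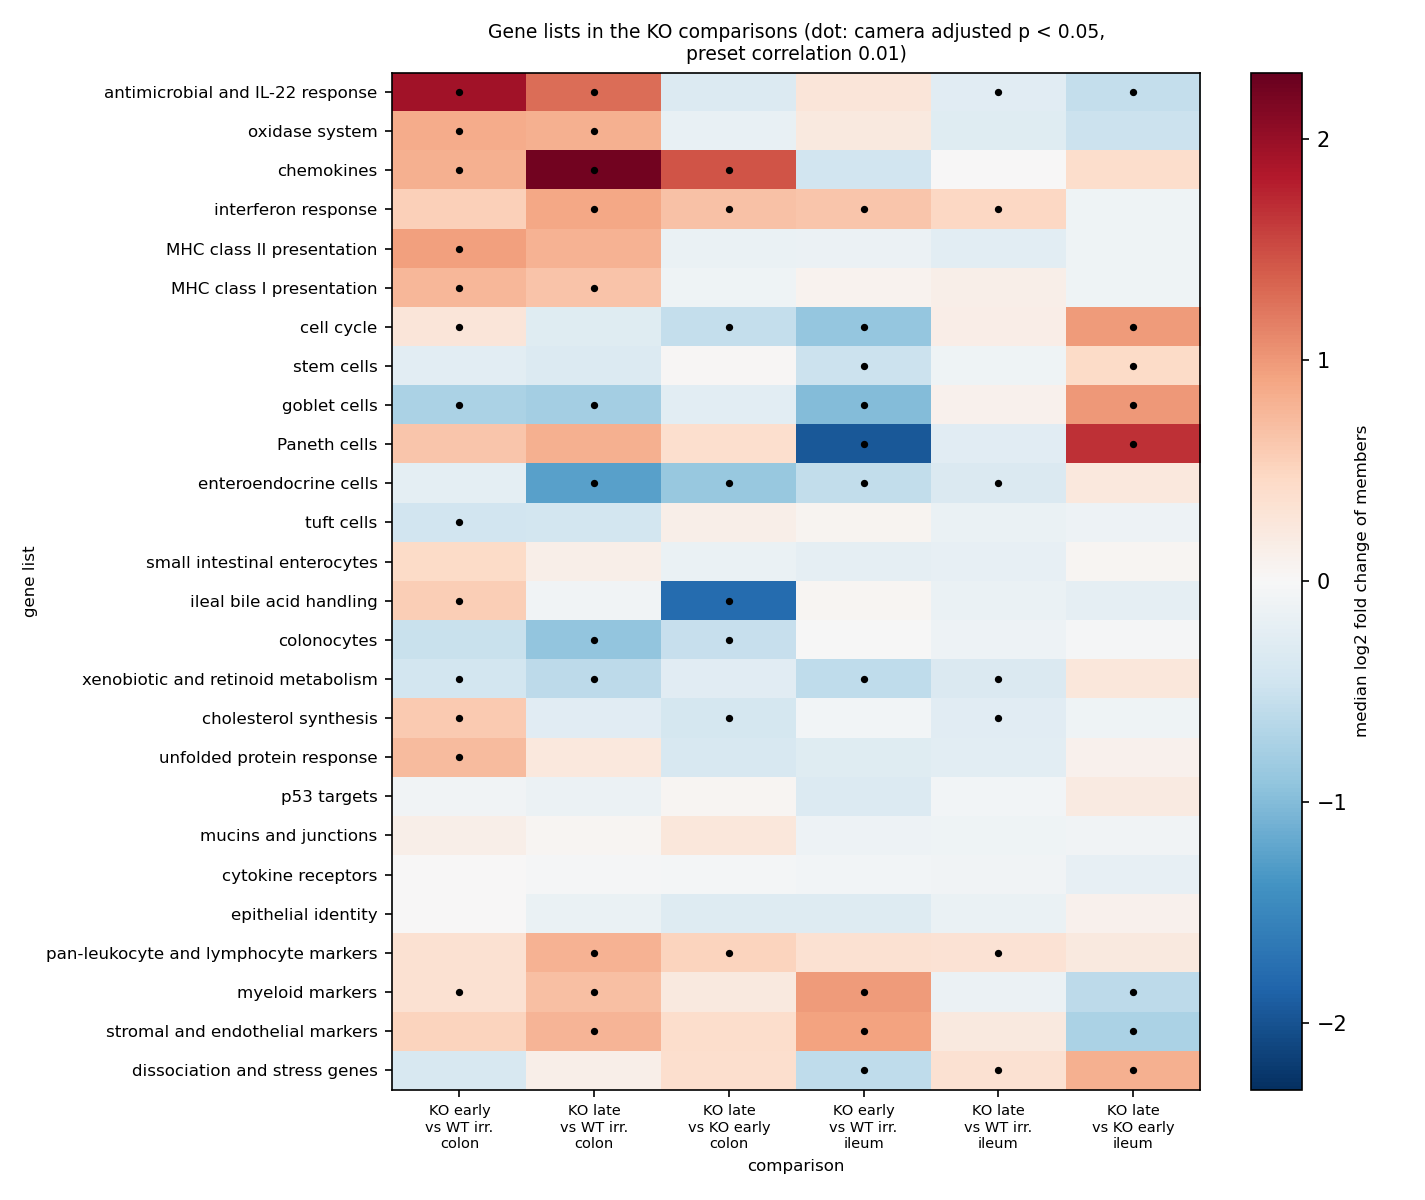
Median log2 fold change of the tested members of 26 gene lists (rows) in 6 KO comparisons (columns), with a dot where the camera adjusted p was under 0.05 at a preset correlation of 0.01. Antimicrobial and IL-22 response genes had medians of 1.94 and 1.29 in KO early and KO late colon and of 0.27 and -0.25 in ileum.

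In ileum, the comparison of KO late with WT irradiated asked the same question as in colon. Reg3b had 139495 ± 62374 normalised reads in KO late and 178189 ± 36493 in WT irradiated, Reg3g had 66624 ± 30406 and 90016 ± 17789, and Clca4b had 33684 ± 2191 and 33906 ± 1768. The WT irradiated ileum thus held more of each than WT irradiated colon, where Reg3b had 826. No gene was called by limma, by edgeR or by DESeq2, with 157 genes at an unadjusted p under 0.05. None of the preset genes tested passed (Il22ra1, Lcn2, Fut2, Saa1, Saa3, Duox2 and Socs3 included), while Cxcl1, Cxcl5 and S100a8 fell under the filter in ileum. The interferon response list lay higher (median 0.47, camera adjusted p = 9.97e-12, adjusted p = 0.711 with an estimated correlation), and the antimicrobial and IL-22 list (-0.25) and that of xenobiotic and retinoid metabolism (-0.34) lay lower, with camera adjusted p of 0.00683 and 2.63e-05 (adjusted p = 0.794 and 0.711 with an estimated correlation). The enteroendocrine, cholesterol, leukocyte and dissociation lists also passed at the preset correlation and not at the estimated one.

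KO early ileum differed from WT irradiated ileum in the lists of dividing and secretory cells. Adjusted over the list alone, 13 of 20 cell cycle genes (median -0.89), 10 of 14 goblet cell genes (-0.99) and 9 of 13 Paneth cell genes (-1.96) were lower and none higher, and over all genes none passed. Their camera adjusted p were 3.99e-07, 6.59e-07 and 2.67e-05, and each had an adjusted p of 0.675 with an estimated correlation. Expressed genes in general shifted the same way, with a median of -0.28 over the 10712 genes with a mean of at least 100 normalised reads. Stem cell genes (-0.50) lay lower as well (camera adjusted p = 0.000464, adjusted p = 0.675 with an estimated correlation). Interferon response (0.64), myeloid (0.99) and stromal (0.93) genes lay higher, with camera adjusted p of 0.000464, 0.0346 and 0.000418 (adjusted p = 0.675 for each with an estimated correlation). The enteroendocrine, xenobiotic and dissociation lists also passed at the preset correlation and not at the estimated one. Reg3b had 208453 ± 68343 normalised reads and was not called. limma called 0 genes, with 4752 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 170, and limma called 6 with receptor reads as a covariate. Receptor reads were 545 ± 201 per M reads in KO early ileum and 290 ± 173 in WT irradiated ileum, and Rn45s, a ribosomal RNA precursor, took 3.81 to 29.4% of KO early and at most 0.549% of WT irradiated reads.

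KO late and KO early ileum were compared in the same lists, with the same 4 KO early libraries, so this comparison does not stand apart from the one above. Adjusted over the list alone, 17 of 20 cell cycle, 12 of 14 goblet cell and 7 of 13 Paneth cell genes were higher in KO late (medians 0.98, 1.00 and 1.67). The camera adjusted p were 1.51e-10, 2.33e-08 and 4.09e-05, and each had an adjusted p of 0.688 with an estimated correlation. Over the 10712 genes with a mean of at least 100 normalised reads the median was 0.19. Dissociation and stress genes (0.82) lay higher too (camera adjusted p = 0.000358, adjusted p = 0.765 with an estimated correlation). The stem cell list (median 0.45) also lay higher, and the antimicrobial (-0.55), myeloid (-0.60) and stromal (-0.72) lists lay lower, with camera adjusted p of 0.000745, 0.0442, 0.0287 and 0.00128 (adjusted p = 0.688, 0.809, 0.688 and 0.733 with an estimated correlation). Over the 47 members of the cell cycle, goblet and Paneth lists the median was -0.96 in KO early against WT irradiated. In KO late against KO early it was 1.02. In simulated unchanged groups that share these libraries the slope between the 2 comparisons was -0.33, a value that group sizes set. That slope times -0.96 gives 0.32, which is not a median of simulated members. Across 19122 genes the 2 comparisons correlated at -0.85, against -0.38 in the simulation, so 0.32 may understate what the shared libraries give. With 2 KO early mice in the first comparison and the other 2 in the second, the medians were -1.34 to -0.55 and 0.71 to 1.38 over the 6 ways to do so, though the lists had been picked with all 4 mice. Background differed too. Receptor reads were 545 ± 201 per M reads in KO early and 380 ± 85.6 in KO late ileum, and Rn45s took 3.81 to 29.4% and 0.283 to 13.6% of reads. limma called 0 genes over all genes, with 4697 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 1353. With a filter of a mean of 100 normalised reads limma called 159, and with receptor reads as a covariate 1327.

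**Figure D3:**
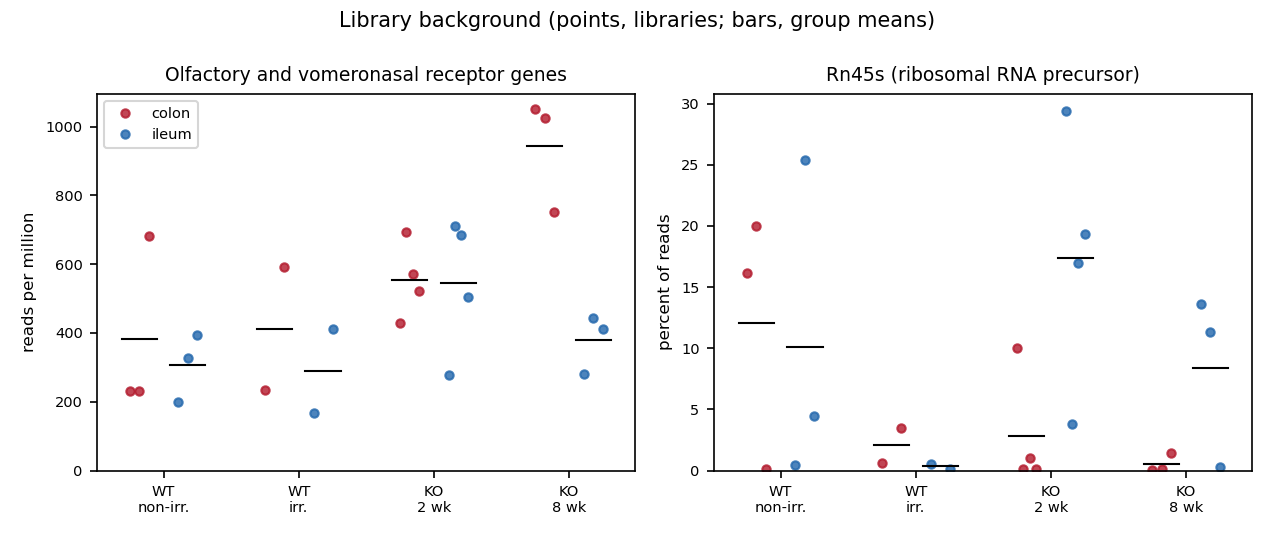
Reads per M in olfactory and vomeronasal receptor genes (left axis panel) and percent of reads on Rn45s (right panel) for each library, with 1 point per library, bars for group means, colon in red and ileum in blue. KO late colon lay between 752 and 1052 reads per M, above every WT colon library (232 to 682), and Rn45s reached 29.4% in 1 KO early ileum library.

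Irradiation and transfer without the knockout were assessed by setting WT irradiated against WT non-irradiated mice. Reg3b in colon had 826 ± 176 and 1764 ± 1597 normalised reads, Clca4b had 314 ± 82.2 and 288 ± 21.0, and Mptx1 had 21856 ± 167 and 36631 ± 14827. No gene was called in colon by limma, edgeR or DESeq2, with 66 genes at an unadjusted p under 0.05. In ileum limma and edgeR called 0 genes and DESeq2 called 2, with 187 at an unadjusted p under 0.05. The MHC class II list had medians of 1.17 in colon and 0.54 in ileum, with camera adjusted p of 6.86e-05 and 0.000196 (adjusted p = 0.389 and 0.873 with an estimated correlation). The interferon response list lay lower in irradiated colon (median -0.39, camera adjusted p = 1.31e-11) and higher in irradiated ileum (0.37, camera adjusted p = 9.67e-06), with adjusted p = 0.389 and 0.873 at an estimated correlation. In colon the antimicrobial, chemokine, MHC class I, goblet, Paneth, enteroendocrine, tuft, enterocyte, colonocyte, cholesterol, p53, mucin and dissociation lists also lay lower and the cell cycle list higher at the preset correlation. In ileum the MHC class I and unfolded protein lists lay higher and the tuft, myeloid and stromal lists lower. None of these passed at the estimated correlation. Many lists thus passed at the preset correlation between WT groups where limma called 0 genes. Such a pass alone does not settle that a list changed, here or in the KO comparisons.

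The epithelia of colon and ileum were compared in WT non-irradiated mice as a baseline. Of 17 small intestinal enterocyte genes, all 17 were lower in colon (median -7.11), 11 of 13 Paneth cell genes were lower and 1 higher (-6.54), and 12 of 15 colonocyte genes were higher and 1 lower (4.70). These calls held in camera with an estimated correlation, with adjusted p = 0.00146, 0.0253 and 0.0253, and so did that of ileal bile acid genes (median -3.07, adjusted p = 0.0273). Of 28 interferon response genes 20 were higher in colon (2.09, camera adjusted p = 9.28e-17, adjusted p = 0.119 with an estimated correlation). Aqp8, a water channel, was 467-fold higher in colon (log2 8.87 ± 0.61), Car1, a carbonic anhydrase, 294-fold (8.20 ± 0.57), and Retnlb, Mptx1, Cyp2d34 and Tgm3 had log2 fold changes of 9.08, 9.01, 8.76 and 7.62. The apolipoprotein genes Apoa1 (-9.24 ± 0.59) and Apoa4 (-8.51 ± 0.68), Enpp7 (-8.66 ± 0.40) and the defensin gene Defa24 (-9.27 ± 1.09) were lower in colon. Defa20 and Defa2 held identical values in every library (-8.60), as near-identical copies that share reads may, so their separate levels are uncertain. limma called 2871 genes (1620 higher and 1251 lower in colon). The count was 1837 and 1879 without mice 72 and 73, and 4624 with receptor reads as a covariate.

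Whether the KO effect differed between tissues was tested as an interaction over all 24 libraries. For KO late, the effect was larger in colon for Clca4b (log2 difference 7.77 ± 0.67, adjusted p = 1.68e-06), Reg3g (7.18 ± 1.07), Reg3b (6.74 ± 1.03), Plet1 (5.92 ± 1.14), Plet1os (5.89 ± 1.09), named as its opposite-strand partner and so uncertain, and Ces2f (4.89 ± 0.87). It was lower in colon for Mptx1 (-7.07 ± 1.40), Slc37a2 (-4.54 ± 0.87), Hao2 (-4.52 ± 0.92), Prss23 (-4.39 ± 0.76), Slc30a10 (-3.94 ± 0.67) and Bmp3 (-2.83 ± 0.48). Mptx1 lay near the filter in KO late and WT irradiated ileum, so its difference mostly restates its fall in colon. Ces2f lay near the filter in KO late ileum. Of 22 antimicrobial and IL-22 response genes 4 had a larger effect in colon, and this list and that of chemokines passed camera with an estimated correlation (adjusted p = 0.0224 for both). Of the 14 chemokines tested here, 10 were tested in ileum alone, where the others fell under the filter. In all 37 genes were called (28 higher, 9 lower), and 130 with the mouse as a block. Leaving out mouse 49, 50, 57, 59 or 61 gave 16, 7, 8, 2 and 1.

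For KO early the interaction called 8 genes. The effect was larger in colon for Clca4b (6.95 ± 0.64), Reg3b (5.91 ± 0.98), Reg3g (5.66 ± 1.01), Clca3b (3.67 ± 0.57), Slc5a9 (2.17 ± 0.36) and Bend7 (1.61 ± 0.29), and lower for Tspan33 (-2.64 ± 0.47). The antimicrobial and IL-22 response list had a median difference of 1.20 (camera adjusted p = 3.86e-10, adjusted p = 0.203 with an estimated correlation), and the cell cycle list of 1.21 (camera adjusted p = 1.72e-10, adjusted p = 0.642 with an estimated correlation). With the mouse as a block 63 genes were called, and 93 by DESeq2. The count was 1 without mouse 59, 117 or 120, 2 without 118, 3 without 61, 15 without 100 and 1 when only these groups were fitted.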

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

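The tests with receptor reads as a covariate, of the background in ileum, of time since irradiation, of neutrophil genes and of wound-associated genes were chosen after the result was seen.

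Of 44 sets of 4 KO early libraries for the named genes, 3 had a library far from the other libraries, in a test that chance alone passes at a rate of 0.05. In colon, Lrg1 had 1836 normalised reads in mouse 118 against 92.2 to 124.9 in the other mice, and Pyy had 81.7 in mouse 120 against 45.7 to 47.4. In ileum, Il22ra1 had 4305 in mouse 100 against 2800 to 2907.

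The interaction test found 19 named differences between colon and ileum in the KO effect. For KO late these were Clca4b (7.77), Reg3g (7.18), Reg3b (6.74), Plet1 (5.92), Plet1os (5.89), Ces2f (4.89), Mptx1 (-7.07), Slc37a2 (-4.54), Hao2 (-4.52), Prss23 (-4.39), Slc30a10 (-3.94) and Bmp3 (-2.83). For KO early they were Clca4b (6.95), Reg3b (5.91), Reg3g (5.66), Clca3b (3.67), Slc5a9 (2.17), Bend7 (1.61) and Tspan33 (-2.64), on the log2 scale.

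The first pattern weighed was the set of genes called in KO late colon, whose libraries had the highest receptor background. The slope of each gene on that background within the 5 WT colon libraries predicted 1.17% of the median change of the 123 higher genes (0.401 to 4.17% when each WT mouse was left out) and 16.6% of that of the 74 lower genes (14.6 to 19.6%). The slope on the Rn45s share predicted 2.37% (-9.25 to 3.13%). With receptor reads as a covariate, 52 of the 123 higher and 8 of the 74 lower genes were still called, 82 genes were called in all (71 higher, 11 lower), and all 197 kept their sign. The median change moved from 2.77 to 2.67 for the higher genes and from -2.19 to -1.74 for the lower genes. Among the 66 lower genes no longer called it moved from -2.09 (SD 1.06) to -1.66 (SD 0.963), with a median standard error of 0.44 before and 0.49 after, so these calls ended through smaller changes with larger errors. The WT colon libraries lay at 232 to 682 receptor reads per M, under the 752 to 1052 of KO late colon. Genes called in this fit were also picked partly for a small spread within groups, which keeps such slopes small. These values therefore do not decide how much of the change either background made, in the higher or the lower genes. The genotype of the chimeras stays open as an untested biological explanation, as does any difference between the KO and WT mice that the labels do not record.

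The second pattern was S100a8 and S100a9, at 4193 and 1039 normalised reads in KO late colon. Neutrophils that passed the CD45-negative gate may have brought them. Of 19 measured neutrophil genes none rose by a log2 fold of 3 and none was called, and their median was 0.82 with a standard error of 0.25, too close to the bound of 1 set for the test to decide. Of the 20 genes listed, 7 stand in other lists used here and 11 had at least 10 normalised reads in WT colon. Il1b and Srgn had log2 fold changes of 2.98 and 2.57, while Lyz2, Tyrobp and Fcer1g stayed at 21.4, 7.90 and 21.8 normalised reads in KO late. The most abundant gene of the list, Cd177, had 2698 in KO late and 583 in WT irradiated colon, so the tissue holds it without KO. A change in the epithelium and carried-over cells cannot be told apart here.

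The third pattern was the lower cell cycle, goblet and Paneth lists in KO early ileum. The slope on receptor background within the 5 WT ileum libraries predicted 47.6% of the median change of the 47 members, and 14.7 to 106% when each WT mouse was left out, which does not decide. Time since irradiation was 2 weeks in KO early and 8 weeks in WT irradiated. The members were higher in KO late than in KO early by a median of 1.02. The slope of -0.33 in simulated unchanged groups, which group sizes set, times the median of -0.96 in KO early against WT irradiated gives 0.32. A shift common to those libraries would give more, so 0.32 does not bound what sharing gives. KO late and WT irradiated differed by a median of 0.059. No WT library at 2 weeks was analysed here, so recovery from irradiation and an early effect of the knockout cannot be told apart. The Rn45s share was 3.81 to 29.4% in KO early and at most 0.549% in WT irradiated ileum. It was not tested as a source of this pattern, so library quality stays open as well.

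Other splits of the libraries were tried where both groups had at least 3. For KO late against KO early colon, 3 of 35 splits gave at least the 1 gene of the real one, so chance could not be excluded. The split of mice 49, 50 and 117 from the others gave 829, which points to a structure among these libraries that crosses the study's groups. These 3 had the lowest Rn45s shares of the 7 (0.0642 to 0.126% against at least 0.163%), and mice 49 and 50 the highest receptor reads (1052 and 1026 per M reads). Whether RNA or library quality makes this structure was not tested. For KO late against KO early ileum all 35 splits gave 0 genes. For colon against ileum in WT non-irradiated mice the 10 splits are too few for a share under 0.05, with 2871 genes for the real split (1 of 10 gave as many) and 2518 for the highest other. That split took both libraries of mouse 72 and 1 of mouse 73 from the rest. Colon 72, colon 73 and ileum 72 had the lowest receptor reads (200 to 233 per M reads against 328 to 682). Which tissue of mouse 73 was in the split was not recorded, so whether it ran along background is open. Of the 4 splits that part every mouse's colon from its ileum, the 3 other than the real one gave 0 genes, and these mix the tissues within a side.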

How the results depend on the processing

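edgeR, TMM scaling, the mean filter and the receptor covariate were chosen after the data were seen. Of 75 named calls none changed direction. All 75 were called by DESeq2, 64 by edgeR, 74 with TMM scaling, 68 without a filter, 59 with only the groups compared, 56 with the covariate and all 31 with the block. Leaving out 1 mouse kept 173 of 374 such values under 0.05. Counts moved as follows, and the cause was not tested unless fewer mice entered. KO late against WT irradiated colon (197) gave 768 with DESeq2, 82 with the covariate, 476 with WT non-irradiated controls, 788 with both WT groups and 11 to 103 without 1 mouse. KO early colon (39) gave 229, 100, 107, 207 and 3 to 73 in the same order, and 23 with only the groups compared. KO early ileum (0) gave 170 with DESeq2 and 6 with the covariate. KO late against KO early colon (1) gave 199 with DESeq2, 9 with the covariate, 3 with only the groups compared, 0 with edgeR, no filter or a mean of 100, and 0 to 16 without 1 mouse. In ileum (0) it gave 1353 with DESeq2, 159 with a mean of 100, 2 with only the groups compared and 1327 with the covariate. WT irradiated against WT non-irradiated ileum (0) gave 2 with DESeq2. Colon against ileum (2871) gave 4624 with the covariate, 1837 to 2725 without 1 mouse, and 3785 with the block. With the block 2 list calls of this comparison were lost (enteroendocrine cells, adjusted p = 0.0793, and mucins and junctions, 0.0518). In the interactions it gained the stromal list for KO late (0.0478) and, for KO early, the colonocyte (0.0204), epithelial identity, goblet and stromal lists (0.0440 each). It changed no other call of a named gene or list. The KO late interaction (37) gave 98 with DESeq2, 63 with the covariate, 130 with the mouse as a replicate block and 1 to 16 without 1 mouse. The KO early interaction (8) gave 93, 32, 63 and 1 to 15, and 1 with only the groups compared.

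A change of sign occurred in 69 values, 63 of them of genes called neither way. For lists this counts the direction of the test, and medians alone are not counted. With the covariate, KO late colon had Il10ra at -0.54, Il22ra1 at 0.33, Saa1 at 0.39, the goblet list at 0.41 and the stromal list at -0.0025, and KO late ileum had Il10ra at -0.36, Fut2 at 0.35, Duox2 at 0.036 and the cholesterol list at 0.059. It also gave Il22ra1 at 0.21 and Lcn2 at -0.31 in KO early ileum, Reg3b at -0.49 and Duox2 at 0.34 in KO late against early colon, and Socs3 at -0.33 in ileum. edgeR and DESeq2 gave Lcn2 in KO late ileum at 0.13 and 0.21, Il22ra1 in KO late against early colon at -0.069 and -0.011, and Socs3 in ileum at -0.037 and -0.072. In KO late ileum, TMM gave Il10ra at -0.0016 and Saa3 at -0.00079, and a pseudocount of 5 gave Lcn2 at 0.034. There, WT non-irradiated controls gave Reg3b, Reg3g, Lcn2, Fut2, Saa3 and Duox2 at 0.69, 0.74, 0.39, 0.24, -0.58 and 0.14, and both WT groups gave the first 5 of them at 0.13, 0.11, 0.17, 0.013 and -0.28. Without 1 mouse, Saa1 in KO late colon lay between -0.63 and 0.15. In KO late ileum the ranges were -0.12 to 0.13 for Saa3, -0.25 to 0.37 for Il10ra, -0.59 to 0.42 for Lcn2, -1.06 to 0.64 for Fut2, -0.70 to 1.56 for Socs3, -0.69 to 0.14 for the cholesterol list, -0.049 to 0.68 for the leukocyte list and -0.24 to 1.00 for the dissociation list. In KO early ileum they were -0.44 to 0.050 for Il22ra1, -0.035 to 0.41 for Reg3b, -0.19 to 0.37 for Reg3g, -0.29 to 1.80 for Saa1 and -1.01 to 1.24 for Socs3. For KO late against early they were -0.51 to 0.049 for Duox2, -0.29 to 0.22 for Il10ra, -0.28 to 0.17 for Il22ra1 and -0.38 to 0.90 for Reg3b in colon, and -0.25 to 0.048 for Il22ra1 and -0.31 to 0.73 for Socs3 in ileum. Of 58 list calls, none held with an estimated correlation. The cause of these changes was not tested.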

Other observations

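The test on wound-associated genes was chosen after the result for some of its genes was seen.

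Of 17 measured genes described in regenerating or wounded epithelium, 4 rose in KO late colon and 2 in KO early colon. Plet1, a surface protein of wound-associated epithelium, had 28671 normalised reads in KO late and 18619 in KO early against 913 in WT irradiated colon (log2 4.93 ± 0.49 and 4.27 ± 0.46, limma adjusted p = 0.000668 and 0.00188). Ly6a rose by 2.66 ± 0.42 and 2.53 ± 0.39 in the same comparisons. Anxa1 (2.25 ± 0.35) and Sprr1a (2.81 ± 0.38) rose in KO late, and in KO early they had 1.11 ± 0.34 and 1.18 ± 0.36 with adjusted p of 0.396 and 0.399. Clu was at 53.9 normalised reads in KO late and 51.3 in WT irradiated colon, and in KO early Clu, Hbegf and Areg had -0.94, -0.64 and -0.32 and were not called.

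The hypothesis was that such genes rise together in both KO groups. From 18 genes, 16 that no earlier list or naming had shown were kept and 15 were tested. In KO late colon the median was 0.82 and the camera p, adjusted over 4 comparisons, 2.27e-06 (adjusted p = 0.212 with an estimated correlation). In KO early colon the median was 0.34 and the adjusted p 0.0740 (0.744 with an estimated correlation), so the prediction of a rise in both was not met. In KO late colon the leukocyte, myeloid and stromal marker lists had medians of similar size (0.79, 0.69 and 0.78), which moved to -0.053, -0.074 and -0.0025 with receptor reads as a covariate. The median of the 15 genes moved from 0.82 to 1.06 (camera adjusted p = 4.91e-06, adjusted p = 0.373 with an estimated correlation), and in KO early it stayed at 0.34 (0.194 and 0.631). The test was first run on the whole list, where 17 of 18 genes were measured, Plet1 and Ly6a among them. That version gave an adjusted p of 3.15e-09 in KO late and 0.000166 in KO early colon (0.126 and 0.269 with an estimated correlation), so the prediction was met with those genes in. They were left out afterwards because their rise had already been seen, which makes them no test of it. In ileum the medians over the 15 genes were 0.022 in KO late and 0.034 in KO early, with an adjusted p of 0.777 for both.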
